A study of Dugesia japonica with 5 samples.

How the data were processed

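Small RNA libraries were made from the planarian Dugesia japonica, a freshwater flatworm that regrows missing body parts from a resident stem cell population. Per the labels, the worms were collected from a creek, were in the asexual stage, were kept in indoor aquaculture at about 20 °C and were starved for 7 days. RNA was taken 3 days after cutting, in a protocol text shared by all 5 samples that does not say how it applied to the whole body. There was 1 library per group: the whole body, the head part and the tail part of a cross cut, and the left part and the right part of a second kind of cut, whose course through the body the labels do not describe. Per the labels' protocols, the libraries were made with an Illumina small RNA kit.

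Each deposited file lists sequences and their read counts. The counts are whole numbers of at least 1, and the deposited counts were used as they stand. The tools that trimmed the reads, the adapter settings and any quality filter are not given in the sources used here. The sequences were 18 to 44 nt long, each occurred once per file, and 842 of them held an N. Reads shorter than 18 nt were not analysed here, and a length limit of the sequencing may end the distribution at 44 nt. No genome was used, so no sequence has a position, a strand or an annotated gene.

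Counts were scaled to reads per 1000000 deposited reads (RPM). miRNA-size groups were reads of 20 to 24 nt sharing their first 18 nt, with at least 500 reads over the 5 libraries. piRNA-size groups were reads of 28 nt or longer sharing their first 25 nt, with at least 100 reads. These size classes are lengths, not annotations, and each holds fragments of other RNAs too. There were 1125 miRNA-size groups, which took 56.7% to 68.4% of the reads of 20 to 24 nt, and 56924 piRNA-size groups, which took 62.6% to 68.6% of the reads of 28 nt or longer. Each group is shown by its most abundant sequence. A conserved family was the sum of reads of 18 to 26 nt that carried nt 2 to 8 of a reference miRNA and matched at least 14 of its first 18 nt. The 47 references were written from textbook sequences of other animals, so a family name here rests on sequence alone. Families were sorted into lists for the nervous system and sense organs, muscle, ciliated cells, gut, developmental timing, invertebrate families and others.

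With 1 library per group there was no replicate check, no test and no p-value. A ratio of RPM carries an exact 95% Clopper-Pearson interval from the conditional binomial distribution, and a share of reads an exact 95% Clopper-Pearson interval. These intervals cover counting error only, because reads copied by PCR are not independent molecules. A group or family was counted as higher or lower by size when its ratio was at least 2 in either direction and the interval excluded 1. For each list the median log2 ratio of its families with at least 100 reads was set beside 10000 random lists of the same size, matched on mean expression by drawing from the 30 nearest groups, with counts of 0 raised to 0.5 reads. The percentile describes these libraries and is not a p-value. The comparisons were each part against the whole body, the head part against the tail part, and the left part against the right part.

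The naming rule, fixed before the data were examined, takes every family with at least 1000 reads over the 5 libraries, in full where it lay 2-fold apart, and the 10 most abundant miRNA-size groups. Per comparison it also takes the 5 highest and 5 lowest miRNA-size groups with a mean of at least 50 RPM, and the 2 highest and 2 lowest piRNA-size groups with a mean of at least 20 RPM, among those counted by size. By a rule added after seeing the data, a sequence is not shown where the tail part lay at least 4 times above the median of the other libraries, or any library at least 8 times above the median of all 5, because such a sequence can come from another organism.

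Fixed marker sequences counted reads of ribosomal RNA (rRNA), transfer RNA (tRNA), U6 RNA, sequencing adapters, bacterial rRNA and vertebrate miRNAs. Further bacterial rRNA markers, a pattern for the 5' fragments of tRNAs cut at the anticodon (the conserved A box of a tRNA near the start of the read) and the precision of a group were added after seeing the data. A group was called precise when at least 80% of all reads holding its first bases started there and fell in its size class. Precise ends are what cutting at a fixed site leaves, and 263 miRNA-size and 31589 piRNA-size groups had them.

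The other settings, fixed at the same time as the naming rule, were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), scaling to the reads of the size class, minimums of 100 reads for miRNA-size and 50 reads for piRNA-size groups, exact sequences, windows of 18 to 25 nt and of 26 nt or longer, distinct sequences, leaving out single-read sequences or marker reads (the added bacterial markers included), and family matching on nt 2 to 8 alone or at 16 of 18 nt. Neither package was used for a test. Alternatives added after seeing the data were counts over precise groups, on all reads and scaled to the reads of those groups, random lists drawn from precise groups, family ratios scaled to the reads of precise groups, list medians under scalings other than TMM, and the parts without the tail part. The counting of calls was tested on simulated counts for the head part against the whole body. The test was first set to ask for 90% of each of 12 simulated classes, and 1 class fell short. The bound was lowered to 80% after that result was seen, with no change to the method, so passing it was not an independent check. Over 1125 miRNA-size groups, 40 of 40 groups were recovered at each of 4-fold up, 4-fold down, 3-fold up and 3-fold down, and 925 of 925 unchanged groups were left uncalled. Over 56924 piRNA-size groups, 40 of 40 groups were recovered at 4-fold up, 39 of 40 at 4-fold down, 39 of 40 at 3-fold up and 33 of 40 (82.5%) at 3-fold down, the class that fell short. Of 56724 unchanged piRNA-size groups 56203 (99.1%) were left uncalled, so counts of piRNA-size groups miss some falls and include some calls made by counting error. A simulated list of 8 unchanged groups lay at percentile 86.7, and the same list raised 3-fold at percentile 100. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Matplotlib 3.10.9 and R 4.3.3.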

Results

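The 5 libraries held 12669775 reads (whole body), 18149423 reads (head part), 17007434 reads (tail part), 17243064 reads (left part) and 15302869 reads (right part), so that 1 read equalled 0.0789 RPM in the shallowest library. Planarians carry miRNAs, which silence target transcripts, and piRNAs, which silence transposable elements and other transcripts in their stem cells. The comparisons ask which small RNAs differ between cut parts and the whole body, and between the parts of each cut. Each group had 1 library, so no difference below has a replicate check, and each ratio compares libraries rather than conditions.

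In all 5 libraries most reads had the length of planarian piRNAs. Reads of 28 nt or longer made up 85.6% of the whole-body library (95% Clopper-Pearson interval 85.60 to 85.64%), 81.8% of the head part, 75.5% of the tail part, 83.5% of the left part and 77.7% of the right part, with a peak at 32 nt. Reads of 20 to 24 nt made up 10.5% of the whole body, 8.42% of the head part, 13.1% of the tail part, 9.69% of the left part and 12.2% of the right part, with a peak at 22 nt. Every interval of these shares spanned less than 0.05 percentage points, so the differences exceed counting error. The reads in between, of 25 to 27 nt, made up 2.32% of the whole body, 8.64% of the head part, 9.60% of the tail part, 5.02% of the left part and 6.76% of the right part.

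**Figure D1:**
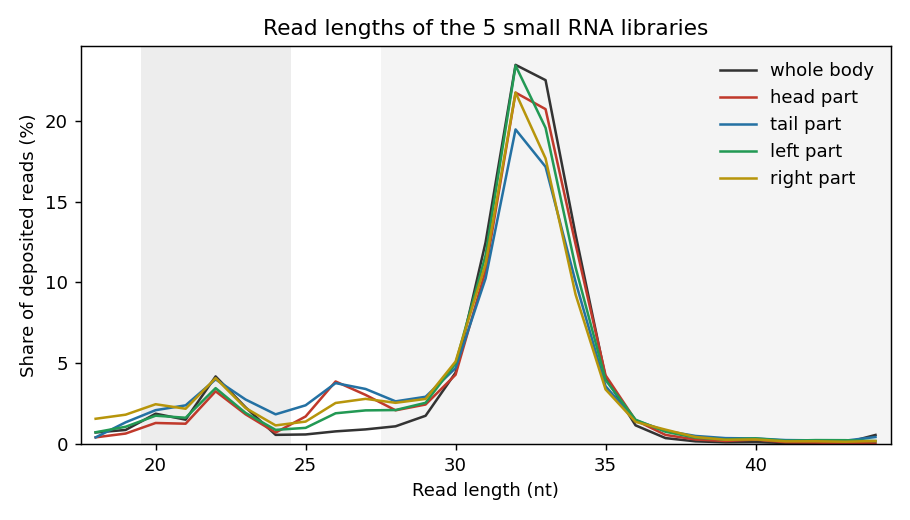
Share of deposited reads (%) by read length (nt) for the 5 libraries, 1 line each, with the 2 size classes shaded. All lines peak at 32 nt, where the whole body stood at 23.4% and the tail part at 19.46%, and at 22 nt. The parts stand above the whole body at 26 nt, with 3.88% in the head part against 0.795% in the whole body.

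Most reads of 28 nt or longer in all 5 libraries, and most reads of 20 to 24 nt in all but the tail part, started with U, the usual first base of animal miRNAs and piRNAs. Of the reads of 28 nt or longer, 78.8% started with U in the whole body, 74.6% in the head part, 68.8% in the tail part, 65.5% in the left part and 61.3% in the right part. With the tRNA-like reads described below left out, the shares were 80.6%, 79.5%, 73.0%, 73.9% and 71.9% in the same order. Among distinct sequences the shares lay closer together, from 69.5% in the tail part to 72.9% in the whole body. Of the reads of 20 to 24 nt, 76.8% started with U in the whole body and 47.0% in the tail part, with the other 3 parts between 68.2% and 74.9%. An A at position 10, the mark of secondary piRNAs made by the ping-pong cycle, was more common among distinct piRNA-size sequences that did not start with U, but not among reads in each library. In the whole body 57.9% of such distinct sequences had it, against 38.4% of those starting with U, after sequences with a tRNA-like start were left out. The shares in the parts were 50.9% to 55.8% against 37.6% to 38.2%. Over reads they were 53.4% against 36.4% in the whole body, 45.7% against 35.1% in the head part, 40.5% against 34.4% in the tail part and 36.4% against 34.6% in the left part, while in the right part the order turned, with 33.3% against 34.4%. With tRNA-like reads included, the share among reads not starting with U was the lower in all 4 parts, from 20.5% against 34.3% in the right part to 34.6% against 35.1% in the head part.

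Structural and foreign RNA differed between the libraries and is given here because it moves with the comparisons below, whose size classes also hold such reads. A marker counts only reads that hold its sequence, so other fragments of the same RNA go uncounted. Reads with a eukaryotic rRNA marker stood at 97.1 RPM in the whole body, 157 RPM in the head part, 871 RPM in the tail part, 178 RPM in the left part and 181 RPM in the right part. Bacterial rRNA markers reached 1748 RPM in the tail part (95% interval 1728 to 1768 RPM), against 13.7 RPM in the whole body, 26.9 RPM in the head part, 34.2 RPM in the left part and 63.9 RPM in the right part. tRNA markers stood at 119 RPM in the whole body, 156 RPM in the head part, 157 RPM in the tail part, 466 RPM in the left part and 533 RPM in the right part. Reads of 28 nt or longer that looked like the 5' fragment of a tRNA cut at the anticodon made up 19938 RPM of the whole body, 51433 RPM of the head part, 44855 RPM of the tail part, 97157 RPM of the left part and 116747 RPM of the right part. Vertebrate miRNA markers stayed between 0.647 and 2.48 RPM, U6 markers between 7.38 and 12.99 RPM and adapter markers between 19.9 and 69.4 RPM.

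**Figure D2:**
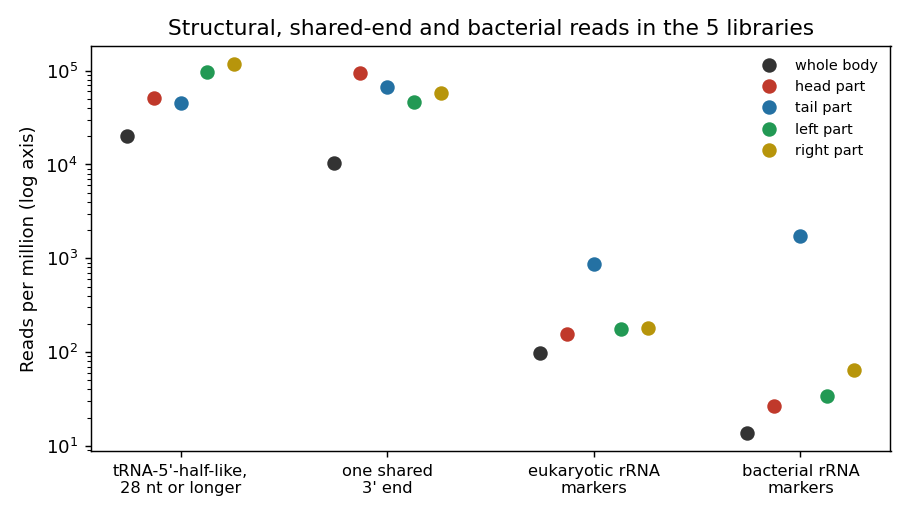
Reads per 1000000 reads (RPM) on a log axis for 4 kinds of reads counted by marker, pattern or shared end, with 1 point per library and no error bars. Those of fitting length are also part of the size classes compared elsewhere. The bacterial rRNA markers stand at 1748 RPM in the tail part and at 13.7 to 63.9 RPM in the other libraries, and the reads with the shared 3' end GGAACTCTAGATAACTTTGC stand at 10487 RPM in the whole body and at 45892 to 95286 RPM in the parts.

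The most abundant miRNA-size group was TCTTACGGCCCCTAAACTTTGGA, which matched no fixed family. It stood at 12184 RPM in the whole body, 7953 RPM in the head part, 5509 RPM in the tail part, 4553 RPM in the left part and 2892 RPM in the right part. It was followed by TGGAATGTCGTGAATTATGGTC (miR-1, the muscle miRNA of most animals; mean 5138 RPM), TGGAAGACTGATGATTTGCTGA (miR-7; mean 5073 RPM) and TGAGGTAGATTGTTGGATGACT (let-7; mean 3429 RPM). Next came TGGACGGAAGTGTAATGAGGGT, which shares nt 2 to 8 with miR-184 but matched no family at 14 of 18 nt (mean 2580 RPM), then TGAGATCACTATGAAAGCTGG (bantam; mean 2178 RPM) and AACCCTGTAGATCCGAGTTTGA (miR-10; mean 1879 RPM). A second let-7 sequence, TGAGGTAGAATGTTGGATGACT, had a mean of 1345 RPM. The list closed with TCAGATCTAACTCTTCCAGTTCT (miR-750; mean 1150 RPM) and TGAAAGACACAGGTAGTGGGAC (miR-71; mean 990.3 RPM). All 10 had precise ends.

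Of the 47 families, 25 had at least 1000 reads and are compared by name. Reads matching any of the 47 stood at 34443 RPM in the whole body, 24288 RPM in the head part, 20767 RPM in the tail part, 25501 RPM in the left part and 28759 RPM in the right part, and the ratio to the whole body was below 1 for 20 of the 25 in the head part, 23 in the tail part, 16 in the left part and 13 in the right part. Reads of precise miRNA-size groups were also highest in the whole body, with 63167 RPM, 45023 RPM, 36008 RPM, 42878 RPM and 47887 RPM in the same order. Scaling to these reads was chosen after seeing the data. Each scaling multiplies all family and miRNA-size ratios of a comparison by 1 constant. For the head, tail, left and right parts against the whole body, TMM multiplied the ratios on all reads by 0.853, 0.394, 0.630 and 0.455, median-of-ratios scaling by 0.852, 0.692, 0.654 and 0.478, scaling to the size class by 1.24, 0.796, 1.08 and 0.860, and scaling to precise groups by 1.403, 1.75, 1.47 and 1.32. Between head and tail part the constants were 2.17, 1.23, 1.56 and 0.7998 in that order of scalings, and between left and right part 1.38, 1.37, 1.254 and 1.12, so how many ratios lie above 1 or past 2-fold rests on the scaling. It also moves the median of all groups: over the 1125 miRNA-size groups the median log2 ratio of the tail part to the whole body was 0.71 on all reads, -0.63 with TMM and 0.18 with median-of-ratios scaling.

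**Figure D3:**
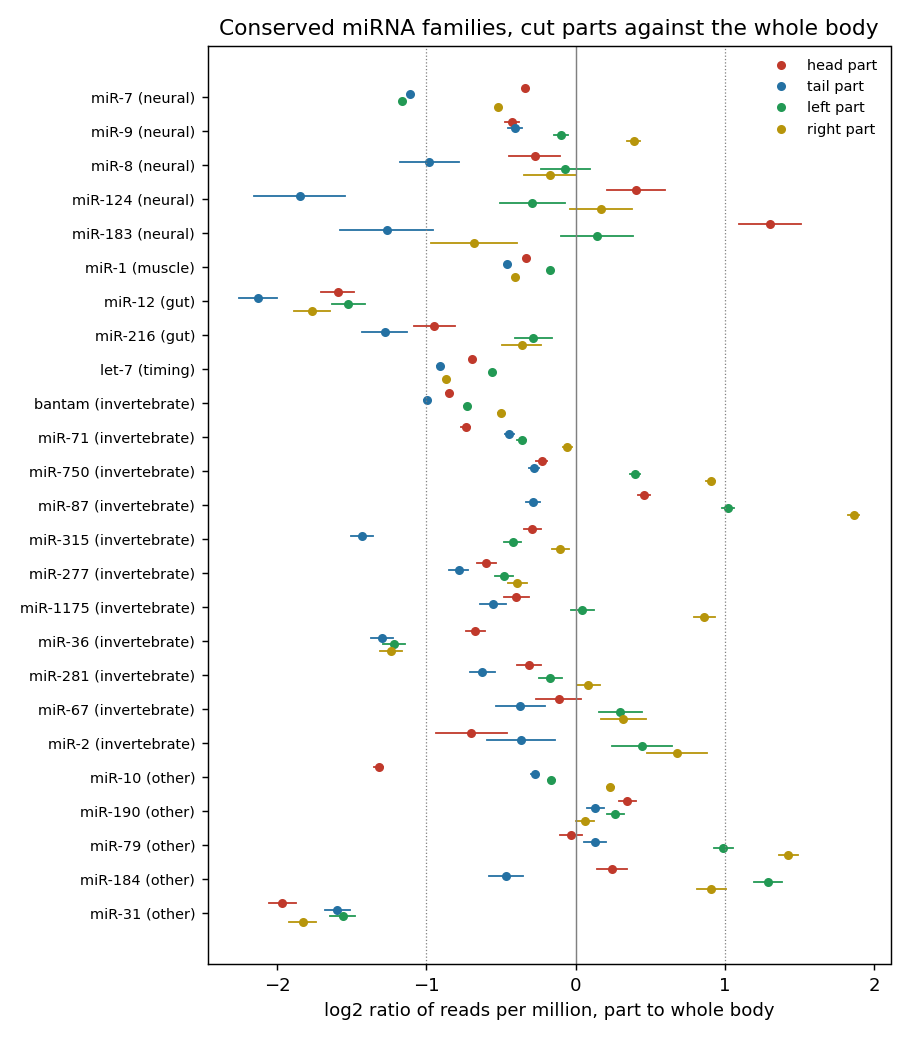
Conserved miRNA families with at least 1000 reads, as the log2 ratio of RPM between each part and the whole body. Points are single libraries, bars are 95% intervals for counting error, dotted lines mark 2-fold, and the list of each family stands in brackets. miR-31 and miR-12 lie left of the 2-fold line in all 4 parts, and miR-87 lies right of it in the left and right parts.

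In the head part against the whole body, miR-183, a miRNA of sense organs in vertebrates, was the 1 named family at least 2-fold higher, and miR-31, miR-12 and miR-10 were at least 2-fold lower. miR-183 stood at 46.7 RPM against 18.9 RPM (2.46-fold, 95% interval 2.13 to 2.86). miR-31 was 3.90-fold lower (interval 3.67 to 4.15), miR-12 was 3.02-fold lower (2.80 to 3.26) and miR-10, encoded among the Hox genes of many animals, was 2.50-fold lower at 889 RPM against 2220 RPM (2.45 to 2.55). Scaled to the reads of precise groups, miR-10 was 1.78-fold lower and no longer 2-fold apart. miR-12 turned to the higher side when 16 of 18 matches were asked for, a rule that kept 12 of its 5561 reads. The other 21 named families lay within 2-fold. Of the nervous system list, 7 of 9 families were detected and 1 was 2-fold higher, with miR-124 at a ratio of 1.32, and the list's median ratio of 0.826 lay at percentile 5.15 of matched lists and at percentile 26.7 among precise groups. That median was 0.704 with TMM and with median-of-ratios scaling, and above 1 when scaled to the size class (1.03) or to precise groups (1.16). The gut list, with 2 of 3 families detected, had a median ratio of 0.415, below all matched lists, or 0.353 to 0.582 in the other scalings.

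By size, 294 miRNA-size groups were higher and 65 lower in the head part, so that 81.9% of the counted groups were higher, against 91.0% when scaled to the size class and 70.2% with TMM. Over precise groups alone the balance turned, with 11 higher and 19 lower, and turned back when these were scaled to their own reads, with 41 and 9. The highest was TATACTGTTGATATGGCATACC at 99.3 RPM against 8.13 RPM (12.2-fold, interval 10.01 to 15.04). The next 4 were nested sequences with a common 3' end, TGGAACTCTAGATAACTTTGC (5.56-fold), GTGGAACTCTAGATAACTTTGC (4.67-fold), TGGTGGAACTCTAGATAACTTTGC (4.38-fold) and GGTGGAACTCTAGATAACTTTGC (3.83-fold). The 5 lowest were the leading sequences of miR-31 (AGGCAAGATGTTGGCATAACTGA), miR-12 (TGAGTATTGCATCAAGGACCGA) and miR-10, with ratios of 0.257, 0.312 and 0.401, and the unmatched CCTCAGATCAGATGCGGCTAT (0.390) and TGGGCTGTTTTGATTCTGTT (0.418). Among piRNA-size groups 2853 were higher and 2975 lower. With TMM 74.7% of the counted groups were higher, and 57.6% when scaled to the size class, against 49.0% on all reads, so the direction of the balance rests on the scaling. Of the higher groups 49.6% started with U, against 82.5% of those within 2-fold. One of the 2 highest piRNA-size groups is not shown, and the other, GTTTTACAATCGTACGTACCATGGAAGTC, stood at 43.5 RPM against 0.868 RPM. The 2 lowest were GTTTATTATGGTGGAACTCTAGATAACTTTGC, at 7.55 RPM against 106 RPM, and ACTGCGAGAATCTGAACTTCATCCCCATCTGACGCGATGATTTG, at 672 RPM against 5458 RPM.

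The tail part had less of 8 named families than the whole body by at least 2-fold and more of none. Among nervous system families, miR-124, a brain and neuron miRNA across animals, was 3.60-fold lower (interval 2.92 to 4.45), miR-183 was 2.40-fold lower (1.94 to 2.99) and miR-7 was 2.15-fold lower (2.13 to 2.18). miR-12 was 4.37-fold lower, miR-31 3.02-fold, miR-315 2.70-fold, miR-36 2.45-fold and miR-216 2.43-fold. The number of families rested on the scaling. With TMM all 25 named families were at least 2-fold lower, with median-of-ratios scaling 14 and scaled to the size class 12. Scaled to precise groups, 2 of the 8 stayed 2-fold apart, miR-124 at 2.05-fold and miR-12 at 2.49-fold, and miR-12 turned to the higher side at 16 of 18 matches, where miR-36 had no reads and miR-216 4 reads. The nervous system list had 4 of 7 detected families 2-fold lower, the fourth being miR-153 (0.823 RPM from 14 reads against 4.81 RPM), and a median ratio of 0.464, or 0.183 with TMM, 0.321 with median-of-ratios scaling, 0.370 when scaled to the size class and 0.814 when scaled to precise groups. On all reads it lay at percentile 0.23 among all other groups but at percentile 22.99 among precise groups. The gut list had both detected families 2-fold lower, with a median ratio of 0.307 at percentile 0.75, and at percentile 2.85 among precise groups, and of 0.121 with TMM to 0.538 when scaled to precise groups.

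Here 530 miRNA-size groups were higher and 206 lower, with 72.0% of the counted groups higher against 45.7% with TMM, 56.8% with median-of-ratios scaling and 61.1% when scaled to the size class. This library also held the most eukaryotic and bacterial rRNA reads. Over precise groups alone 7 were higher and 109 lower, and 14 and 21 when scaled to their own reads, the opposite balance. The 5 highest groups are not shown. They stood at 108 to 314 RPM in the tail part, against 0 to 3 reads in the whole body. The 5 lowest were TGTAAAACTTTCTGTATATT (0.209), TCCCTGAGACCATTGACTGTAT, which shares nt 2 to 8 with miR-125 (0.216, or 328 RPM against 1519 RPM), the miR-12 sequence (0.224), TAACATAGGAATGTATAATA (0.226) and the miR-31 sequence (0.348). Among piRNA-size groups 3790 were higher and 8904 lower, and 34.0% of the higher groups started with U. With TMM 66.8% of 8412 counted groups were higher, and 43.8% when scaled to the size class, against 29.9% on all reads. The 2 highest are not shown. The 2 lowest were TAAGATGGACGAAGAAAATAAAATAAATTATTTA (0.111) and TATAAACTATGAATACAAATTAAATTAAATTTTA (0.121).

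In the left part against the whole body, miR-184 was 2.44-fold higher (interval 2.29 to 2.60) and miR-87 was 2.03-fold higher (1.97 to 2.09), while miR-31, miR-12, miR-36 and miR-7 were lower. miR-31 was 2.95-fold lower (2.79 to 3.12), miR-12 2.87-fold, miR-36 2.32-fold and miR-7 2.24-fold (2.22 to 2.26). With TMM scaling the higher families were under 2-fold, miR-184 at 1.54-fold and miR-87 at 1.28-fold, as with median-of-ratios scaling (1.60-fold and 1.33-fold). miR-87 was 1.61-fold higher at 16 of 18 matches, a rule that kept 516 of its 74643 reads. miR-184 turned to the lower side when matched on nt 2 to 8 alone, a rule that adds an abundant unmatched sequence. Scaled to precise groups, miR-12, miR-36 and miR-7 were 1.95-fold, 1.58-fold and 1.52-fold lower. miR-36 was also under 2-fold on nt 2 to 8 alone (1.96-fold). So was miR-7 at 16 of 18 matches (1.65-fold), which kept 1338 of its 416905 reads. The nervous system list had 1 of 7 families 2-fold lower and a median ratio of 0.818, or 0.515 with TMM, 0.535 with median-of-ratios scaling, 0.883 when scaled to the size class and 1.21 when scaled to precise groups. Of the timing list, which holds let-7, miR-100 and miR-125, miR-100 was 2.51-fold higher (interval 1.78 to 3.62), with 147 reads in the left part, but 1.58-fold with TMM and 1.64-fold with median-of-ratios scaling, and let-7 stood at 4835 RPM against 7125 RPM.

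By size 468 miRNA-size groups were higher and 87 lower, with 84.3% of the counted groups higher against 56.2% with TMM and 58.9% with median-of-ratios scaling. The balance turned over precise groups alone, with 28 higher and 40 lower, and turned back when these were scaled to their own reads, with 51 and 15. Of the higher groups 5.98% had precise ends. The groups were not matched to rRNA sequences, so those named next may be rRNA fragments. The 5 highest were CAACTTTGAGCGGTGGATCACTC (20.2-fold, interval 15.7 to 26.5), AGGACGGTGGCCATGGAAGTCGG (16.3-fold), CACATCTGTCTGAGGGTCGGC (14.4-fold), CAGGACGGTGGCCATGGAAGTCGG (12.0-fold) and ACATCTGTCTGAGGGTCGGC (11.1-fold), none of them with precise ends. The 5 lowest were the sequence that shares nt 2 to 8 with miR-125 (0.292), the miR-12 sequence (0.332), the miR-31 sequence (0.350), the most abundant group TCTTACGGCCCCTAAACTTTGGA (0.374) and CGAAGATCGGAACTGTGGGG (0.390). Among piRNA-size groups 4604 were higher and 9203 lower, and with TMM 66.5% of the counted groups were higher against 33.3%. The 2 highest were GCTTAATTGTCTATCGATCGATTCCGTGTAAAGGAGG (31.3-fold) and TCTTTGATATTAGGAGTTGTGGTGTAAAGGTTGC (27.8-fold). The 2 lowest were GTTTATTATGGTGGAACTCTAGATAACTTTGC (0.112) and TTCGATTGCTTGAACTACATGACTGAACA (0.131).

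In the right part miR-87 was 3.64-fold higher than in the whole body (interval 3.54 to 3.74) and miR-79 was 2.69-fold higher (2.57 to 2.81), and both were under 2-fold with TMM (1.65-fold and 1.22-fold) and with median-of-ratios scaling (1.74-fold and 1.28-fold). miR-31 was 3.55-fold lower (3.33 to 3.79), miR-12 3.40-fold lower and miR-36 2.36-fold lower, with miR-12 again on the higher side at 16 of 18 matches. miR-36 was 1.79-fold lower when scaled to precise groups and 1.82-fold lower on nt 2 to 8 alone. With TMM 15 named families were at least 2-fold lower, and scaled to precise groups 6 were higher and 2 lower. On all reads no nervous system family with at least 1000 reads was 2-fold apart, and the list's median ratio was 0.937, or 0.426 with TMM, 0.447 with median-of-ratios scaling, 0.806 when scaled to the size class and 1.24 when scaled to precise groups. Of the muscle list, miR-1 stood at 5425 RPM against 7199 RPM, and miR-133, with 531 reads in all, was 2.66-fold higher (interval 1.99 to 3.59), but 1.21-fold with TMM and 1.27-fold with median-of-ratios scaling.

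Here 616 miRNA-size groups were higher and 64 lower, with 90.6% of the counted groups higher against 57.5% with TMM and 60.4% with median-of-ratios scaling. Among precise groups 67 were higher and 23 lower. Of the 5 highest, 3 are not shown. The others were TTTGATGACTCTGGATAATTTTAC (20.4-fold) and TTGATGACTCTGGATAATTTTAC (14.3-fold). The 5 lowest were CGAAGATCGGAACTGTGGGG (0.105), TTTGGCACTGAAGGAATCGTCAC, which shares nt 2 to 8 with miR-96 (0.226), TCTTACGGCCCCTAAACTTTGGA (0.237), the miR-12 sequence (0.272) and the sequence that shares nt 2 to 8 with miR-125 (0.280). Among piRNA-size groups 5012 were higher and 20014 lower, the highest number in any comparison. With TMM 58.8% of 17608 counted groups were higher, against 20.0% on all reads. The 2 highest are not shown. The 2 lowest were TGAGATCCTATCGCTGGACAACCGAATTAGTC (0.0872) and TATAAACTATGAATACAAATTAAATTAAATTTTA (0.0962).

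On all reads, 3 of the 7 detected nervous system families were at least 2-fold higher in the head part than in the tail part. miR-183 was 5.92-fold higher (interval 4.93 to 7.16), miR-124 was 4.76-fold higher at 35.0 RPM against 7.35 RPM (3.92 to 5.81), and miR-153 was 7.63-fold higher, with 14 reads in the tail part (4.37 to 14.4) and none in any library at 16 of 18 matches. With TMM the ratios of miR-183 and miR-124 were 12.8 and 10.3, with median-of-ratios scaling 7.30 and 5.86, scaled to the size class 9.23 and 7.42, and scaled to precise groups 4.74 and 3.81. Of the other members of that list miR-7 stood at a ratio of 1.70, miR-8 at 1.63 and miR-9 at 0.987. In all 3 planned scalings miR-7 was past 2-fold, at 3.69 with TMM, 2.10 with median-of-ratios scaling and 2.66 when scaled to the size class. So was miR-8, at 3.53, 2.01 and 2.54 in the same order. Scaled to precise groups miR-7 stood at 1.36 and miR-9 at 0.789, while the other scalings put miR-9 above 1. The median ratio of 1.70 lay at percentile 98.7 among all other groups but at percentile 47.3 among precise groups, which were themselves mostly higher in the head part. It was 3.69 with TMM, 2.10 with median-of-ratios scaling, 2.66 when scaled to the size class and 1.36 when scaled to precise groups. miR-315 was 2.21-fold higher in the head part, and 1.77-fold when scaled to precise groups. miR-10 was the 1 named family 2-fold lower, at 889 RPM against 1836 RPM (2.06-fold lower, interval 2.03 to 2.10), but under 2-fold in all 3 planned scalings, 1.68-fold lower with median-of-ratios scaling, 1.32-fold lower when scaled to the size class and on the other side with TMM (ratio 1.05), while scaled to precise groups it was 2.58-fold lower. With TMM 20 of the 25 named families were at least 2-fold higher in the head part, with median-of-ratios scaling 7 and scaled to the size class 9. The muscle miRNA miR-1 stood at a ratio of 1.09. That ratio was 2.37 with TMM, 1.35 with median-of-ratios scaling and 1.70 when scaled to the size class. It was 0.874 when scaled to precise groups and 2.41 at 16 of 18 matches, which kept 10055 of the 477157 miR-1 reads. miR-133, with 38 reads in the tail part, was 2.17-fold higher in the head part. It was 1.74-fold higher when scaled to precise groups and 1.91-fold on nt 2 to 8 alone.

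By size 157 miRNA-size groups were higher and 455 lower in the head part than in the tail part. With TMM 56.2% of 940 counted groups were higher, and 45.6% when scaled to the size class, against 25.7% of 612 on all reads. Over precise groups alone the direction was the opposite, with 86 higher and 5 lower, or 50 and 6 when scaled to their own reads. The 5 lowest are not shown and stood at 101 to 225 RPM in the tail part against 2 to 13 reads in the head part. The 5 highest were TGTAAAACTTTCTGTATATT (3.75-fold), TAACATAGGAATGTATAATA (3.42-fold), the sequence that shares nt 2 to 8 with miR-125 (2.83-fold), TGTCATCAAATCATCTGAATGT (2.78-fold) and TGAGCTGTCTAAAGTCTAAACA (2.73-fold), all with precise ends. Among piRNA-size groups 4386 were higher and 2656 lower, and 31.8% of the lower groups started with U against 82.2% of the higher ones. With TMM 40.6% of the counted groups were higher, and 51.4% when scaled to the size class, against 62.3% on all reads. One of the 2 highest piRNA-size groups and both of the 2 lowest are not shown, and the other high one was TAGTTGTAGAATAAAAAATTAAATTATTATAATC (4.77-fold).

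Between the left part and the right part, no named family was 2-fold apart on all reads. The widest ratios were miR-87, 1.79-fold lower in the left part (interval 1.76 to 1.83), miR-183, 1.77-fold higher (1.47 to 2.12) and past 2-fold in all 3 planned scalings (2.44-fold with TMM, 2.42-fold with median-of-ratios scaling and 2.21-fold when scaled to the size class), and miR-1175, 1.76-fold lower (1.69 to 1.84). miR-7 was 1.56-fold lower and miR-750 1.42-fold lower in the left part. The families miR-2, miR-67, miR-71, miR-277 and miR-281 lay within 1.24-fold and changed side with the scaling. The other named families, miR-8, miR-9, miR-10, miR-190, miR-216 and miR-315 among them, lay within 1.401-fold. Of these, bantam, miR-10, miR-79, miR-124 and miR-315 also changed side with TMM.

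By size 68 miRNA-size groups were higher and 274 lower in the left part. With TMM 49.6% of the counted groups were higher, with median-of-ratios scaling 47.7% and scaled to the size class 39.8%, against 19.9% on all reads. The 5 highest were AGGACGGTGGCCATGGAAGTCGG (4.91-fold), CGAAGATCGGAACTGTGGGG (3.71-fold), TATACTGTTGATATGGCATACC (2.32-fold), CAGGACGGTGGCCATGGAAGTCGG (2.30-fold) and AACAATGTAGGTAAGGGAAGTCGG (2.01-fold). Of the 5 lowest, 3 are not shown, and the others were TGGTTACTGTGGGCAACTCA (0.321) and AGCTGAGAAATCTGTAATTA (0.350). Among piRNA-size groups 6664 were higher and 1450 lower, with 44.4% of the counted groups higher under TMM and 71.9% when scaled to the size class, against 82.1% on all reads. The 2 highest were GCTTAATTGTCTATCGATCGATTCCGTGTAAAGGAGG (7.33-fold) and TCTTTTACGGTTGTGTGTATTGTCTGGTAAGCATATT (6.90-fold), and the 2 lowest are not shown.

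All 4 parts lay at least 2-fold from the whole body on the same side for 253 miRNA-size groups, 228 of them higher and 25 lower. The 4 comparisons share 1 whole-body library, so part of this count can come from that library alone. Simulated unchanged groups gave 0 such groups, but they vary by counting error only. Independent lists would share 31.5 higher and 0.0524 lower groups, but the 4 lists share the whole-body library. Neither figure holds variation between libraries, so neither tells what the count means. With the tail part as the reference, 455 groups had all other libraries on 1 side, against 8 for the head part, 24 for the left part and 77 for the right part. With TMM 69.3% of such groups were higher, and with median-of-ratios scaling 73.4%, against 90.1% on all reads. Without the tail part the number was 272. Of the 228 higher groups, 2 had precise ends, and of the 25 lower groups 9, so that the balance turned, and scaled to their own reads precise groups gave 7 higher and 3 lower. Both miR-31 sequences and the miR-12 sequence were the most abundant of those 9. AGGCAAGATGTTGGCATAACTGA stood at 232 RPM in the whole body and 59.6 to 81.3 RPM in the parts, AGGCAAGATGCTGGCATAGCTGA at 59.99 RPM and 12.1 to 17.1 RPM, and TGAGTATTGCATCAAGGACCGA at 162 RPM and 36.3 to 53.8 RPM. Scaled to precise groups the first, which is the most abundant, was 1.64-fold lower in the tail part and 1.94-fold lower in the left part and so dropped out, while the other two stayed at least 2-fold lower in all 4 parts. Among piRNA-size groups 1331 were higher and 1021 lower in all 4 parts. Simulated unchanged data gave 24.9 and 1.35 groups and independent lists 1.35 and 26.5, with the same limits. With the right part as the reference the number was 3299, above the 2352 of the whole body. With TMM 91.9% of such piRNA-size groups were higher, and 70.7% when scaled to the size class, against 56.6% on all reads. Among precise groups 408 were higher and 612 lower, and the balance turned back when these were scaled to their own reads, with 512 and 397.

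The gut list had median ratios of 0.535 in the left part and 0.478 in the right part, or 0.337 and 0.2175 with TMM, 0.350 and 0.229 with median-of-ratios scaling, 0.577 and 0.412 when scaled to the size class and 0.788 and 0.631 when scaled to precise groups. All 3 families of the ciliated cell list, miR-29, miR-34 and miR-92, had fewer than 100 reads. The invertebrate list had 12 of 17 families detected, with median ratios to the whole body of 0.709 in the head part, 0.664 in the tail part, 0.957 in the left part and 1.15 in the right part. The timing list of 3 families had median ratios of 0.634, 0.502, 1.13 and 1.03 in the same order, and the muscle list of 2 families 0.888, 0.576, 1.23 and 1.42. The sides of several of these medians rested on the scaling or on the matching rule. The timing list's medians in the left and right parts were the ratios of miR-125, which had 860 reads. Matched on nt 2 to 8 alone, miR-125 had 128933 reads and lay below the whole body. It then stood at 1414 RPM in the left part and 1585 RPM in the right part, against 2673 RPM in the whole body. With TMM the invertebrate list stood at 0.604, 0.261, 0.603 and 0.523, the timing list at 0.541, 0.198, 0.711 and 0.471, and the muscle list at 0.757, 0.227, 0.774 and 0.643, in the same order of parts. Scaled to precise groups the lists stood at 0.994, 1.17, 1.41 and 1.52, at 0.890, 0.881, 1.66 and 1.37, and at 1.245, 1.01, 1.81 and 1.87.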

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

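All tests in this part were chosen after the results were seen, as were the tRNA pattern, the shared 3' end and some of the bacterial markers.

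Bacterial rRNA markers, which no compared family or list covers, lay above the whole-body level of 13.7 RPM in all 4 parts, with 1748 RPM in the tail part, 34.2 RPM in the left part, 63.9 RPM in the right part and 26.9 RPM in the head part (1.96-fold, interval 1.65 to 2.35). Such reads of fitting length also enter the size-class groups, as do those of the next 2 kinds. In the tail part 16 of 16 bacterial markers stood at least 10 times above the median of the other libraries. RNA of bacteria in that library would give such levels. Markers of bacterial 16S rRNA from the fixed set alone stood at 82.3 RPM in the tail part, against 1.74 to 4.38 RPM in the other libraries. The rest of the 1748 RPM includes 616 RPM from 16S markers added after seeing the data, so the count of 16 is no independent check. Breakdown of the worm's own RNA is argued against, because the bacterial markers were 127-fold above the whole body (95% interval 110 to 149) while eukaryotic rRNA markers were 8.97-fold above it, single ones going both ways from 0.118-fold to 21.1-fold. Bacteria that tail tissue carries in uncut worms are argued against as well, because the highest level among the whole body, left part and right part was 3.66% of the tail part's, and the whole body holds tail tissue. Bacteria at every wound alike are argued against, because the head, left and right parts were cut too and stood at 26.9, 34.2 and 63.9 RPM. Bacteria at the tail part's own wound, in the water or in the reagents stay open and untested, with 1 tail library.

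Reads like 5' fragments of tRNAs lay above the whole-body level of 19938 RPM in all 4 parts, with 51433 RPM in the head part (2.58-fold), 44855 RPM in the tail part (2.25-fold), 97157 RPM in the left part (4.87-fold) and 116747 RPM in the right part (5.86-fold). Of 323 piRNA-size groups of this kind, 155 were higher and 19 lower in the head part, 161 and 14 in the tail part, 250 and 3 in the left part, and 248 and 2 in the right part.

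Reads ending in GGAACTCTAGATAACTTTGC also lay above the whole-body level of 10487 RPM in all 4 parts, with 95286 RPM in the head part (9.09-fold), 66335 RPM in the tail part (6.33-fold), 45892 RPM in the left part (4.38-fold) and 58468 RPM in the right part (5.58-fold). They took 76.8% of the reads of 25 to 27 nt in the head part and 24.3% in the whole body.

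The ratio of miR-2 to the whole body lay below 1 in both parts of the cross cut and above 1 in the left and right parts, with mean log2 ratios 1.09 apart, and that of miR-750 did the same, with means 0.90 apart. The difference was not tested. Of 25 named families 2 had this pattern or its reverse with all 4 intervals excluding 1. miR-67 and miR-1175 lay on the same sides, but not all of their intervals excluded 1. If signs were random and independent, 12.5% would have either by side alone. But the 2 families were also held to their intervals, and the signs share the whole-body library, so this share is no fair measure. With TMM scaling or with scaling to precise groups 0 of these 2 kept the pattern. Scaled to the size class, miR-2 kept it and miR-750 did not. Matched on nt 2 to 8 alone, miR-2 had 79840 reads instead of 2106 and lost the pattern. It then stood at 1261 RPM in the whole body. All parts were lower, at 762 RPM (head), 945 RPM (tail), 1117 RPM (left) and 960 RPM (right). Under that rule miR-750 kept its sides, with 1039 RPM in the whole body. Its head and tail parts stood at 887 and 945 RPM, and its left and right parts at 1368 and 1927 RPM.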

How the results depend on the processing

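Counts over precise groups, scaling to their reads, lists drawn from them, list medians other than with TMM or 16 of 18 matches, and the parts without the tail part were chosen after seeing the data, and all other alternatives were planned. No paired analysis was possible because each group had 1 library. Scaling to the size class, and for miRNA-size groups counting exact sequences, kept each sum of higher and lower groups within 1.5 times of its main value, as did leaving out the tail part for the groups shared by all parts. The cause was not tested for any change below unless it is stated. Depth limits the piRNA-size counts, since a group can enter with 100 reads over 5 libraries, and 7 of 40 simulated 3-fold falls at that setting were missed.

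With minimums of 100 and 50 reads more groups entered, and 1231 miRNA-size groups were counted in the head part, 3207 in the tail part, 2151 in the left part and 2726 in the right part against the whole body, 2687 between head and tail part, 1353 between left and right part and 665 in all 4 parts. The piRNA-size counts were 12031, 23314, 24680, 41697, 14244, 14650 and 4072 in the same order. Over precise groups alone, which are fewer by construction, the miRNA-size counts were 30, 116, 68, 90, 91, 61 and 11 and the piRNA-size counts 2862, 5952, 7203, 14430, 2814, 4591 and 1020. Scaled to the reads of those groups they were 50, 35, 66, 122, 56, 45 and 10 for miRNA-size and 2761, 3856, 7905, 14422, 1964, 3921 and 909 for piRNA-size groups.

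TMM scaling gave 940 miRNA-size groups between head and tail part and 8412 piRNA-size groups between tail part and whole body, where median-of-ratios scaling gave 8433. The window of 18 to 25 nt gave 1046 miRNA-size groups in the right part against the whole body and 571 between left and right part.

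Counts of higher or of lower groups taken singly moved more than their sums. By over 1.5 times, 22 of 28 such counts moved with TMM, 19 of 28 with median-of-ratios scaling, 7 of 28 when scaled to the size class and 0 of 14 with exact sequences. Scaled to the size class, lower miRNA-size groups went from 65 to 38 in the head part and from 206 to 322 in the tail part against the whole body, higher ones from 157 to 357 between head and tail part, and higher and lower ones from 68 and 274 to 107 and 162 between left and right part. Lower piRNA-size groups went from 8904 to 5561 in the tail part and from 1021 to 643 in all 4 parts. With TMM the higher and lower miRNA-size groups were 240 and 102 in the head part, 441 and 525 in the tail part, 310 and 242 in the left part, 351 and 259 in the right part, 528 and 412 between head and tail part, 128 and 130 between left and right part, and 140 and 62 in all 4 parts. The piRNA-size groups were 4106 and 1392, 5616 and 2796, 6936 and 3498, 10359 and 7249, 2281 and 3340, 2772 and 3472, and 2254 and 199 in the same order. With the window of 18 to 25 nt, lower miRNA-size groups were 110 in the head part and 336 in the tail part, higher ones 968 in the right part and lower ones 483 between left and right part.

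The share of reads in the miRNA-size window was 12.67% in the whole body, 11.2% in the head part, 17.3% in the tail part, 12.5% in the left part and 17.0% in the right part with the wider window. It was 7.24%, 7.18%, 9.65%, 9.04% and 12.0% over distinct sequences, and 11.2%, 8.56%, 13.8%, 9.71% and 12.1% without single-read sequences. The piRNA-size share was 87.3%, 88.8%, 82.7%, 87.5% and 83.0% with the wider window, 88.1%, 87.96%, 83.6%, 84.7% and 79.1% over distinct sequences, and 85.2%, 80.8%, 73.9%, 83.4% and 77.6% without single-read sequences. Without marker reads the tail part's shares were 13.1% and 75.5%, which moved by more than their narrow intervals.

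Among families, the log2 ratio of miR-10 between head and tail part was 0.0696 with TMM scaling. At 16 of 18 matches, which kept 12 reads of miR-12, its log2 ratio to the whole body was 1.80 in the head part, 0.58 in the tail part and 1.73 in the right part. With nt 2 to 8 alone, the log2 ratio of miR-184 in the left part was -0.65, because the rule adds the abundant TGGACGGAAGTGTAATGAGGGT. Of the 27 calls of named families in 5 comparisons, TMM scaling ended 5, median-of-ratios scaling 5 and scaling to the size class 1. Matching on nt 2 to 8 alone ended 3, 16 of 18 matches 10 and scaling to precise groups 12. At 16 of 18 matches no reads of miR-36, 4 of miR-216, 516 of miR-87 and 1338 of miR-7 were left. Over all 6 comparisons the same settings added 54, 28, 13, 1, 8 and 6 calls in that order.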

Other observations

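All tests in this part were chosen after the results were seen, and the sequences in its first paragraph were chosen after their values were seen.

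Reads of the opposite strand to the shared 3' end had fixed 5' ends, unlike the shared-end reads themselves. They stood at 19.7 RPM in the whole body, 10.03 RPM in the head part, 20.4 RPM in the tail part, 53.1 RPM in the left part and 34.4 RPM in the right part, and AGCAAAGTTATCTAGAGTTCCA was the most abundant of them in 4 of the 5 libraries. Between 99.7% and 100% of these reads started at the same base. Among tRNA-like reads, the second most abundant sequence starting with CCGGTG kept between 58.4% and 61.6% of the level of the first in all 5 libraries, while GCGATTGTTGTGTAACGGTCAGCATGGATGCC ranged from 18.13% to 31.7% of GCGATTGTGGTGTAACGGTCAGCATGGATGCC. A miR-9 sequence, TCTTTGGTATTCTAGCTGTAGA, stood at 49.1 RPM in the left part and 10.3 RPM in the whole body (4.75-fold, interval 3.95 to 5.76). The miR-9 family as a whole did not rise with it, at 508 RPM in the left part and 544 RPM in the whole body.

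The 228 miRNA-size groups higher in all 4 parts may hold more fragments of longer RNA, since 0.877% of them had precise ends against 23.4% of all groups. Scaling to all deposited reads is argued against as the whole cause, because 140 groups were higher in all 4 parts with TMM. The whole-body library by itself cannot be told apart from a difference between cut and whole worms, because there was 1 such library. No other library as the reference gave more than 48 groups higher in all the rest. With the tail part as the reference, however, 407 groups were lower in all the rest, so another single library stood apart for more groups than the 228. A biological difference between cut and uncut worms stays open and untested.

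Of the 7 detected nervous system families, 3 were at least 2-fold higher in the head part than in the tail part on all reads. These were miR-183, miR-124 and miR-153. The 3 were picked for high ratios, so what follows is no independent check. Scaling to precise groups, which gauges dilution of the tail part's miRNAs by other RNA, multiplies every ratio by the same 0.7998. It left the lowest of these 3 ratios at 3.81. Families picked at 2-fold or more could not come near 1 under that constant, so this outcome was fixed by the picking. It shows only that the 3 ratios exceed a dilution of that size and does not decide on dilution as a cause. The rest of the list is not covered, and miR-9 stood at 0.789 in that scaling. More of these miRNAs in head tissue would place the whole body between head and tail part. That held for all 3, for none of the other 4 detected families and for 5 of the 25 named families. The 3 were picked for wide ratios between head and tail part, where another library falls in between more easily. The contrast with the other families is therefore no support. On all reads the placing held beyond counting error for 2 of the 3, not for miR-153 (4.81 RPM in the whole body and 6.28 RPM in the head part). With TMM or median-of-ratios scaling the interval of miR-124 between head part and whole body included 1, which left miR-183 alone. Scaling to the size class or to precise groups instead raises the ratios of head part to whole body, by 1.24 and 1.403. The number of families placed beyond counting error therefore rests on the scaling. With 1 library each, more of these miRNAs in head tissue cannot be told apart from other differences between the libraries and stays open. The list's median lay at percentile 47.3 among precise groups.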
